A study of Mus musculus with 12 samples.

How the data were processed

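Liver RNA of male mice was hybridised to 12 one-colour Agilent arrays, 1 sample per array. Per the labels, the animals were 3-month-old C57BL/6 mice lacking the glucocorticoid receptor (GR) in the liver, and 4 samples each came from animals given PBS, an adeno-associated virus carrying GFP (AAV-GFP) or one carrying human GR beta (AAV-hGRB). Per the labels' protocols, total RNA was prepared with a Qiagen RNeasy kit with DNase treatment, and 500 ng was labelled with Cy3. The labels number the samples of a group but do not say that each came from an animal of its own, so the p-values measure the spread between these samples. How long after injection the livers were taken, and the vector dose, are not given in the sources used here.

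The deposited scanner files hold spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction 9.5.3.1 subtracted the local background and detrended each array, and spots not above background received a surrogate value. The submitters' processing notes name Feature Extraction 9.5. Each array held 43379 non-control spots, and 1639 control spots were left out. The deposited series matrix comes without a stated scale or centring. Compared spot by spot, its 540216 values equal the processed intensity of the scanner files within a relative 1e-06, so its scale is linear with no centring between arrays, and using it changes nothing. Its column medians were 51.7, 43.6, 28.4 and 43.1 for AAV-GFP replicates 1 to 4, 43.9, 50.9, 54.4 and 57.1 for AAV-hGRB, and 67.1, 58.9, 38.9 and 47.9 for PBS.

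From the processed intensity, log2 values were taken, spots of the same probe were averaged (245 probes have several spots, and spots marked as outliers by the scanner software were left out where another remained) and the array's 75th percentile over all probes was subtracted. Of 41174 probes, 26593 were well above background on at least 4 of the 12 arrays and were tested, and 14581 were not. Probes were named through the RefSeq accession the array design gives: 22951 matched by their systematic name and 124 by another accession, and 18099 kept the name of the array design. The reference table, built on GRCm38.p6, was used for names only. Probe coordinates are those of the file headers' design, on the mouse build mm7. Where a gene has several probes, the probe of highest mean signal stands for it, and the values of other probes are given for some genes.

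All 12 arrays entered a single limma fit (limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of the data.table package), with 3 groups, no further term and 9 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. The comparisons were AAV-hGRB against AAV-GFP, AAV-GFP against PBS and AAV-hGRB against PBS. The samples' groups, the tests, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined.

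For each of 29 gene lists, chosen for liver metabolism, glucocorticoid and interferon responses, stress pathways and the cell types of liver and its neighbours, limma's camera tested whether the list's genes shifted against all other genes, with a preset correlation of 0.01 and adjustment over the 29 lists. Beside it stand camera with a correlation estimated from the arrays, limma's fry, which asks whether the members move on balance in 1 direction, and an exact permutation test of the mean of the list over the 70 arrangements of 4 against 4 arrays, whose smallest p is 0.0286. Counts of members called after adjustment over the list alone are given beside the count over all probes. Named genes are the 12 with the largest rise and the 12 with the largest fall among those past the threshold with no overlap between groups, or 8 and 8 in the comparisons with PBS. Where fewer than 5 passed in a direction, the 5 of lowest unadjusted p are named as not past the threshold, and predicted or clone names were skipped. Nr3c1, Pck1, G6pc, Fkbp5, Tsc22d3 and Per1 are always named, with up to 4 members of each list. Some genes that this rule names are not reported here.

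Where a probe was well above background on 0 of the 4 arrays of a group, its change against that group is given as "at least" a fold. For this bound each of those arrays was set to the lowest signal among its probes well above background, or to the probe's own value if that was higher.

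The fit and the list tests were checked on simulated data with the real probes' levels and spread, in 10 draws. With 100 probes changed per fold, the AAV-hGRB against AAV-GFP fit over 26593 probes recovered 9.3% of those changed 2-fold and 60.3% of those changed 4-fold, with 1.6 false calls per draw on average. In AAV-hGRB against PBS the same values were 12.1%, 62% and 1.4. In the AAV-hGRB against AAV-GFP draws, camera with the preset correlation called a list shifted by 1 log2 unit in 10 of 10 draws but also called 6.2 of the other lists on average. With an estimated correlation it called the shifted list in 0 of 10 draws and 0 others. In the AAV-GFP against PBS draws, where no list was shifted, 7 other lists were called on average with the preset correlation, and the interferon list, left unshifted, in 6 of 10 draws.

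The 75th percentile of the processed intensity ran from 220.1 (AAV-GFP replicate 3) to 631.7 (AAV-hGRB replicate 3), and 55.3% to 66.9% of the spots were well above background. The arrays lay on 6 slides. Slide 5 held AAV-GFP replicate 2, AAV-hGRB replicate 1 and PBS replicate 4, slide 6 held replicate 3 of each group, slide 1 held AAV-GFP replicate 1 and PBS replicate 2, and slide 3 held AAV-hGRB replicates 2 and 4. Slides 2 and 4 held 1 array each, PBS replicate 1 and AAV-GFP replicate 4. With the slide as a fixed block, arrays that share no slide with another group do not inform a group difference. The blocked comparisons of AAV-hGRB thus rest on AAV-hGRB replicates 1 and 3, and a call lost with the block need not reflect an effect of slides. AAV-GFP replicate 4 alone was scanned on another day, so scan day cannot be separated from that array. Without it, 149 of 159 results kept their direction and side of the threshold, 7 fell short of it and 3 turned sign. These results are 139 changes of single genes and 20 called lists other than the interferon list. No gene passed in the reported fit, so all 7 that fell short are lists. Correlations between arrays ran from 0.905 to 0.986 over the tested probes.

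The alternatives were quantile and median scaling, normexp background correction with an offset of 50 on the mean and background signals, no filter or a stricter filter on dim probes, the slide as a fixed or random block, the replicate number as a block, an intensity trend with robust hyperparameters, array weights, a fold minimum of 1.5, an unadjusted p under 0.01, 1 probe per gene, only the 2 groups compared, and leaving out each array. Principal components as covariates, quantile scaling with a trend, and both control groups pooled were added after the data were seen. Figures were drawn with matplotlib 3.10.9.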

Results

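The series holds 12 liver transcriptomes, 4 each from GR liver-knockout mice given PBS, AAV-GFP or AAV-hGRB. Its title asks what human GR beta, a splice form of the glucocorticoid receptor that does not bind glucocorticoids, does to transcription where GR alpha is absent. AAV-hGRB against AAV-GFP addresses that question, AAV-GFP against PBS measures what a vector with an unrelated cargo does, and AAV-hGRB against PBS gives a further control. Values are log2 intensity minus the array's 75th percentile. With 4 arrays per group, the number of arrays limits the precision, and the median standard error of a log2 change was 0.31.

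The targeted gene, Nr3c1 on chromosome 18, was read by 4 probes, all within 39787242 to 39790865 (mm7). On the brightest probe its level was 0.40 ± 0.16 in AAV-hGRB, 0.34 ± 0.20 in AAV-GFP and 0.37 ± 0.15 in PBS (SD, n = 4), with single arrays between 0.05 and 0.58. The array has no probe stated to lie in the deleted part and no wild-type group, so these levels check neither the knockout nor the transgene. The change of that probe was 0.07 against AAV-GFP (adjusted p = 0.998), -0.03 for AAV-GFP against PBS and 0.04 for AAV-hGRB against PBS, and the sign of each turns under other settings. The other 3 probes, all dimmer, stood at 0.47, 0.42 and 0.27 against AAV-GFP, 0.09, -0.27 and 0.01 for AAV-GFP against PBS, and 0.56, 0.14 and 0.27 for AAV-hGRB against PBS.

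In AAV-hGRB livers, genes induced by interferon were higher than in AAV-GFP livers. All 30 tested members of the interferon-induced list had a positive change, with a median of 1.31 (2.49-fold). The list mean was 2.69 ± 0.66 in AAV-hGRB and 1.30 ± 0.19 in AAV-GFP (SD, n = 4). Each of the 4 AAV-hGRB arrays lay above each AAV-GFP array. Ifi44, Ifit1 and Irf7 stood 7.07-, 5.66- and 5.62-fold higher, Usp18, which removes the ubiquitin-like ISG15 from proteins, 4.68-fold, and Isg15 itself 4.16-fold.

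The list rose by camera (adjusted p = 5.4e-53), and it was the only 1 of the 29 to keep its call with an estimated correlation (adjusted p = 0.0429 with an estimated correlation) and with fry (adjusted p = 0.0469). Its exact permutation p was 0.0286, the smallest that 4 against 4 can give. Of its members, 23 rose when adjusted over the list alone and 0 over all probes. Usp18 (log2 change 2.23, SE 0.38) and Irf7 (2.49, SE 0.43) had the lowest list-alone adjusted p, 0.00122 each, followed by Oasl1 (1.70) and Ifi44 (2.82). Bst2, Psmb8, Stat2, Psmb9, Iigp1 and Irf1 were among those that did not pass. Within slide 5 the list's median difference between 1 AAV-hGRB and 1 AAV-GFP array was 0.82, and within slide 6 it was 1.79. With the slide as a block, where only AAV-hGRB replicates 1 and 3 inform the difference, the median was 1.33 and camera's adjusted p 1.14e-22. The list-alone count then fell to 0 of 30.

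**Figure D1:**
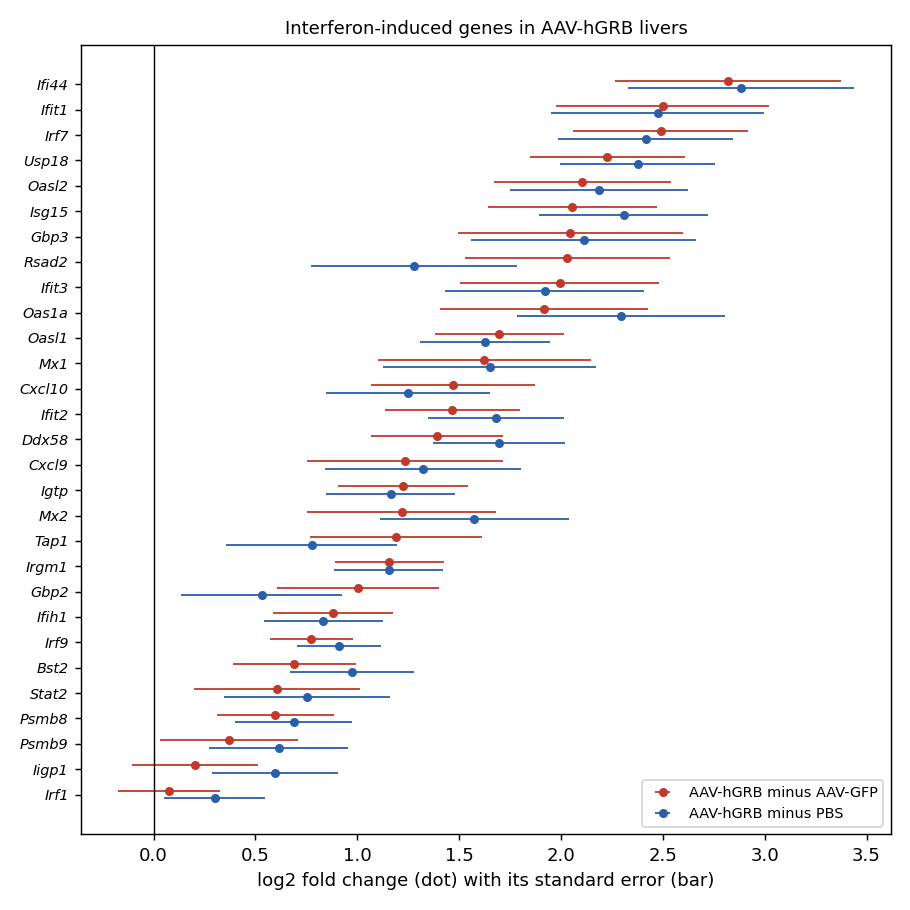
Log2 fold change (x axis) of 29 of the 30 tested interferon-induced genes (y axis) in AAV-hGRB against AAV-GFP (red) and against PBS (blue), with dots for limma's estimate and bars for its standard error (n = 4 arrays per group). All 29 dots lie above 0 in both comparisons, with Ifi44 at 2.82 and 2.88.

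Targets of p53 also rose against AAV-GFP. Of 17 tested members 14 were positive, with a median of 0.35 (camera adjusted p = 7.29e-08, adjusted p = 0.0798 with an estimated correlation). Adjusted over the list alone 4 members rose, and over all probes 0. They were Cdkn1a, the cell cycle inhibitor p21 (1.88, 3.67-fold), Phlda3, an inhibitor of Akt (1.49), Mdm2, the ligase that degrades p53 (0.83), and Eda2r, a receptor of the TNF family (2.26). The list mean was 1.42 ± 0.28 in AAV-hGRB and 0.91 ± 0.21 in AAV-GFP (SD, n = 4, exact permutation p = 0.0571). Its median was 0.22 within slide 5 and 0.76 within slide 6, and 0.33 with the slide as a block (adjusted p = 0.000462). Normexp background correction gave a median of 0.21 (adjusted p = 3.02e-05).

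Markers of 3 leukocyte classes were higher than in AAV-GFP as well, with no member past the threshold when adjusted over the list alone or over all probes. T cell and NK cell markers rose by a median of 0.41 (15 of 17 positive, camera adjusted p = 1.31e-07, adjusted p = 0.118 with an estimated correlation, exact permutation p = 0.0286). Ccl5 stood at 1.15 and the granule protease Gzma at 1.52. Without AAV-hGRB replicate 3 the T and NK median was 0.23 (adjusted p = 4.63e-05), and with the slide as a block 0.68 (0.29 within slide 5, 0.62 within slide 6) and with normexp 0.22. Kupffer cell and macrophage markers rose by 0.33 (16 of 16, adjusted p = 0.000191, adjusted p = 0.348 with an estimated correlation, exact permutation p = 0.229). Their call was lost without AAV-GFP replicate 1 (median 0.19, adjusted p = 0.0655), and the median was 0.53 without AAV-hGRB replicate 1 and 0.20 without AAV-hGRB replicate 3. It was -0.31 within slide 5, 0.65 within slide 6 and 0.30 with the slide as a block, and 2 principal components as covariates ended the call (adjusted p = 0.0818). Neutrophil markers rose by 0.23 (5 of 8, adjusted p = 0.0266, adjusted p = 0.305 with an estimated correlation, exact permutation p = 0.4), led by S100a8 (0.88) and S100a9 (0.86). That call was lost without AAV-GFP replicate 1 or 2 or AAV-hGRB replicate 4 (adjusted p = 0.1 to 0.133), with the slide as a block (0.33, adjusted p = 0.117), with 1 or 2 principal components as covariates (adjusted p = 0.0589 and 0.0922) and with no filter on dim probes, which turned its sign (-0.12, adjusted p = 0.0649). The neutrophil median was 0.72 within slide 5 and -0.29 within slide 6, 0.05 without AAV-GFP replicate 2, 0.41 without AAV-GFP replicate 3, 0.49 with array weights and 0.86 with the stricter filter. Against PBS the neutrophil markers of AAV-hGRB stood lower, with a median of -0.40 (8 of 8 negative), and those of AAV-GFP lower still (-0.89).

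The gluconeogenesis list and the fatty acid oxidation list stood lower in AAV-hGRB than in AAV-GFP, with calls that depended on the settings. The gluconeogenesis list fell by a median of 0.25 (15 of 20 members negative, camera adjusted p = 0.0266, adjusted p = 0.159 with an estimated correlation). Its mean was 4.81 ± 0.08 against 5.07 ± 0.15 (SD, n = 4, exact permutation p = 0.0571). No member passed over the list alone or over all probes. G6pc, the final enzyme of glucose release, stood at -1.38 (SE 0.57), Pck1, its rate-limiting enzyme, at -0.62 (SE 0.27, or -0.39 without AAV-GFP replicate 3), the tyrosine aminotransferase gene Tat at -0.75 and Creb3l3 at -0.38. In AAV-hGRB against PBS, G6pc and Pck1 were near even, at -0.08 and 0.10. Fatty acid oxidation and PPARA targets fell by 0.23 (19 of 22, adjusted p = 0.0266, adjusted p = 0.565 with an estimated correlation, exact permutation p = 0.314), with Angptl4 at -1.02 (0.08 against PBS), Acaa1b at -0.62 and Cpt2 at -0.46. In AAV-hGRB against PBS that whole list stood at -0.28 (18 of 22 negative, camera adjusted p = 0.0714, not called), and in AAV-GFP against PBS at 0.01. Quantile scaling ended both calls, with medians of -0.08 (adjusted p = 0.609) and -0.09 (adjusted p = 0.491). The slide as a block ended them too, at -0.38 (adjusted p = 0.117) and -0.17 (adjusted p = 0.508), as did median scaling (adjusted p = 0.054 each) and no filter on dim probes (adjusted p = 0.15 each), and 2 principal components ended the fatty acid call (adjusted p = 0.0818). Within slides 5 and 6 the gluconeogenesis median was -0.50 and -0.07, and the fatty acid median -0.93 and 0.83, which turns its direction. The gluconeogenesis call was lost without AAV-GFP replicate 1, 2 or 4 or AAV-hGRB replicate 1 or 4 (adjusted p = 0.0618 to 0.201), and its median was -0.16 without AAV-GFP replicate 2. The fatty acid call was lost without AAV-GFP replicate 1, 2 or 4 or AAV-hGRB replicate 1 (adjusted p = 0.137 to 0.425). Its median was -0.13 and -0.10 without AAV-GFP replicates 1 and 2, -0.48 without AAV-GFP replicate 3, -0.42 with array weights and -0.36 with normexp.

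The other called lists were small. Erythroid genes fell by 0.52 (6 of 6, adjusted p = 0.0308, adjusted p = 0.359 with an estimated correlation), with the haem synthesis gene Alas2 at -0.55 and the anion exchanger Slc4a1 at -0.65. The erythroid call was lost without AAV-GFP replicate 1, 2 or 4 or AAV-hGRB replicate 4 (adjusted p = 0.0655 to 0.126), with quantile scaling (-0.30, adjusted p = 0.0547), with median scaling (adjusted p = 0.0734) and with the first principal component (adjusted p = 0.079). Cholangiocyte markers fell by 0.69 (9 of 11, adjusted p = 0.0401, adjusted p = 0.207 with an estimated correlation), with the keratins Krt23 and Krt19 at -1.35 and -1.20 and Muc1 at -0.94. That call was lost without AAV-GFP replicate 2, 3 or 4, AAV-hGRB replicate 1 or 2, or PBS replicate 3 (adjusted p = 0.0547 to 0.425), and the median was -0.28 without AAV-GFP replicate 2. Normexp cut the cholangiocyte median to -0.08 (adjusted p = 0.195), and no filter (adjusted p = 0.117), the stricter filter (adjusted p = 0.262) and 1 or 2 principal components (adjusted p = 0.11 and 0.0818) ended its call as well. NRF2 targets rose by 0.11 (11 of 14, adjusted p = 0.0266, adjusted p = 0.305 with an estimated correlation), led by the glutathione transferase Gsta1 (1.48). That call was lost without AAV-GFP replicate 1 (0.03, adjusted p = 0.135) or 3 (0.05, adjusted p = 0.267), and the median was 0.21 and 0.06 without AAV-GFP replicate 2 and AAV-hGRB replicate 2 and 0.28 with quantile scaling. Normexp (median 0.001, adjusted p = 0.344), array weights (adjusted p = 0.237), median scaling (adjusted p = 0.054) and 2 principal components (0.05, adjusted p = 0.183) ended the NRF2 call too. With the slide as a block the medians were -0.61, -1.02 and 0.02, and none of the 3 lists kept its call (adjusted p = 0.117, 0.0887 and 0.141). Within slides 5 and 6 the erythroid median was -0.10 and -0.36, the cholangiocyte median -1.46 and -0.44, and the NRF2 median -0.09 and 0.36.

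Genes induced by glucocorticoids did not shift as a list (median -0.16, 11 of 19 negative, camera adjusted p = 0.361, exact permutation p = 0.514). Adjusted over the list alone Cdkn1a, which is also in the p53 list, rose, and Angptl4 and Tat fell. Over all probes 0 passed. Among the members named in advance, the log2 change was 0.08 for Fkbp5 (SE 0.62), -0.14 for Tsc22d3 (SE 0.33) and -0.33 for Per1 (SE 0.56, n = 4, limma adjusted p = 0.998 each), and the signs of these 3 turned under other settings. G6pc and Pck1 stood at -1.38 and -0.62 (limma adjusted p = 0.998 each). Against PBS they stood at -0.08 and 0.10, and AAV-GFP lay above PBS by 1.29 and 0.72. Tat was at -0.75 (adjusted p = 0.0476 over the list alone). Over their 3 probes each, Fkbp5 ran from -0.14 to 0.81 and Tsc22d3 from -0.14 to 0.11.

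The remaining 18 lists were not called. Male-biased liver genes, which follow growth hormone, came nearest (median -0.29, adjusted p = 0.0559), then hepatocyte core genes (-0.19, 0.132) and acute phase genes (0.16, 0.179). An adjusted p of 0.204 belonged to glycolysis and lipogenesis (-0.21), cholesterol synthesis (0.11), bile acid genes (-0.23), B cell and plasma cell markers (-0.04) and endothelial markers (-0.02). Camera's direction for the B cell and endothelial lists was up, as were their means of 0.12 and 0.03. Cd22 rose by 0.87 when adjusted over the B cell list alone. Stellate cell (0.04, 0.228), xenobiotic metabolism (0, 0.232), adipocyte (-0.06, 0.248), MHC class II (0.04, 0.361), circadian clock (-0.25, 0.44), cell cycle (0.01, 0.457), immediate early and heat shock (-0.19, 0.579), female-biased (-0.01, 0.83), ER stress (-0.10, 0.87) and pancreatic acinar genes (-0.22, 0.959) followed, each with its median and adjusted p. Camera's direction was up for the female-biased and ER stress lists, whose medians and means (-0.09 and -0.05) were negative, and for the cell cycle list, whose mean was -0.02.

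**Figure D2:**
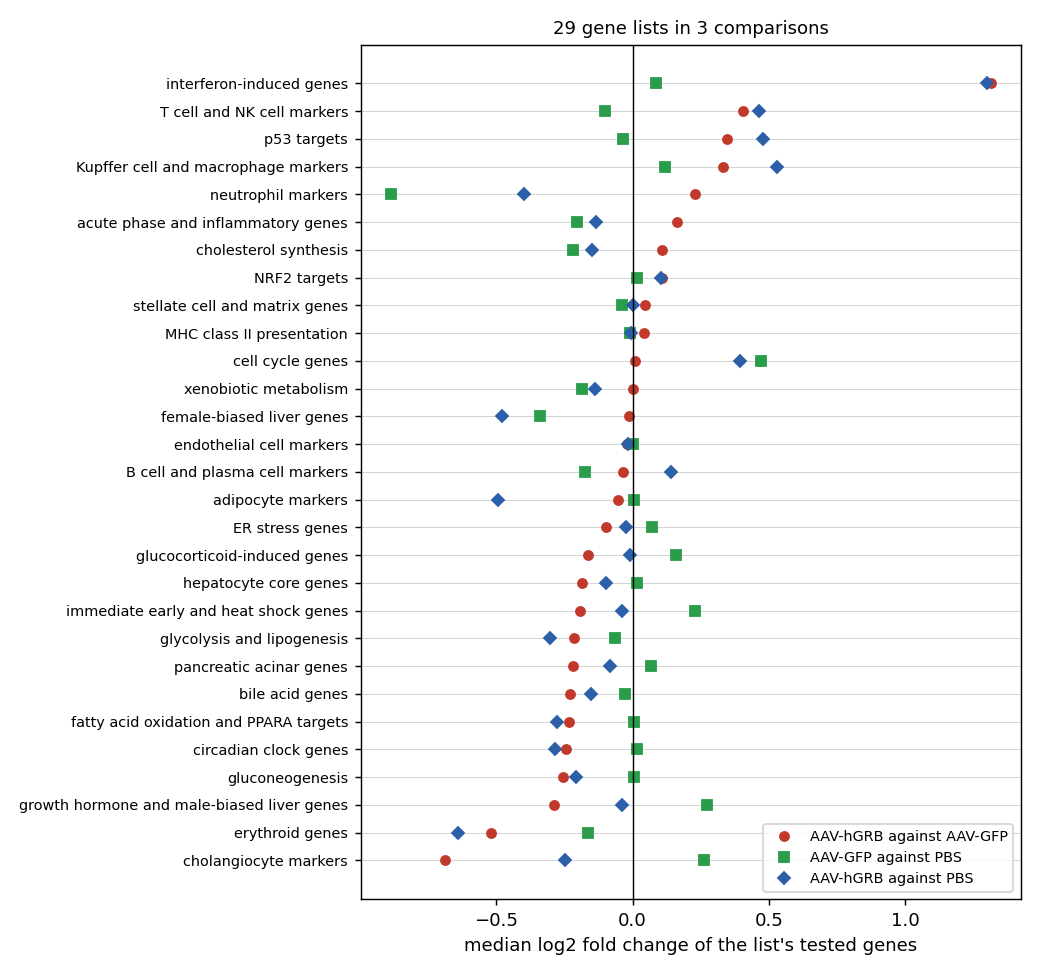
Median log2 fold change (x axis) of the tested genes of each of the 29 lists (y axis) in the 3 comparisons, 1 marker per comparison. The interferon list stands at 1.31 and 1.30 in the comparisons of AAV-hGRB with AAV-GFP and PBS, and at 0.09 in AAV-GFP against PBS.

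No single probe passed the threshold. Limma called 0 of 26593 probes (lowest adjusted p = 0.31), and 892 had an unadjusted p under 0.05 where 1330 would be expected by chance. At an unadjusted p under 0.01 there were 211, 166 of them higher, where 266 would be expected. The groups did not overlap for 793 probes (2.98%), against 2.86% by chance. The genes of lowest p among those higher were Samd9l (3.34-fold, SE of the log2 change 0.28), Fbxo39 (3.73-fold, SE 0.30), Usp18, Irf7 and the RNA editing enzyme Adar (2.02-fold, with its 2 probes at 0.56 and 1.01), at limma adjusted p of 0.31 to 0.398. Those lower were the mitochondrial carrier Slc25a25 (-1.73, with its 3 probes at -1.73 to -1.31), the carbonic anhydrase Car14 (-1.14), Krt14 (-1.29), the kinase Wnk4 (-0.90) and Akr1c21 (-0.95), at adjusted p of 0.659 to 0.898. On the Slc25a25 probes AAV-GFP lay above PBS by 1.05 to 1.32 and AAV-hGRB stood at -0.41 to -0.26 against PBS, so most of that difference is between AAV-GFP and PBS. Wnk4 likewise stood at 0.55 in AAV-GFP against PBS and -0.35 in AAV-hGRB against PBS, while Car14, Krt14 and Akr1c21 stood at -0.79, -1.18 and -0.71 in AAV-hGRB against PBS. Camera's preset correlation called 10 lists, but in the simulated data it called 6.2 unshifted lists on average and another grouping of the same 8 arrays gave 17, and the count was 4 without AAV-GFP replicate 1 and 6 without AAV-GFP replicate 4. Blocked by slide, limma called 0 probes, 114 probes had an unadjusted p under 0.01, and camera called 4 lists.

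AAV-GFP livers differed little from PBS livers in the interferon list. Its median change was 0.09 (19 of 30 positive, camera adjusted p = 0.736), its means were 1.30 ± 0.19 and 1.26 ± 0.30 (SD, n = 4, exact permutation p = 0.83), and 0 members passed over the list alone. The difference of the means was 0.05, with a 95% confidence interval of -0.65 to 0.74. Within slides 1, 5 and 6 the median was -0.37, -0.08 and 0.29, and without AAV-GFP replicate 3 or PBS replicate 1 it was -0.01 and -0.05.

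Cell cycle genes were higher in AAV-GFP than in PBS, by a median of 0.47 (17 of 18, camera adjusted p = 9.4e-06, adjusted p = 0.404 with an estimated correlation, exact permutation p = 0.143). Foxm1, which drives mitotic genes, stood at 0.65, Cdc20 at 0.91, Plk1 at 0.77 and the proliferation marker Mki67 at 0.70, and 0 members passed over the list alone or over all probes. The slide block gave 0.54 (adjusted p = 6.31e-06), normexp 0.27 (adjusted p = 0.000119), and slides 1, 5 and 6 gave 0.46, 0.35 and 0.59. Neutrophil markers fell by 0.89 (7 of 8, adjusted p = 1.02e-06, adjusted p = 0.0912 with an estimated correlation), or -0.93 with the slide as a block. Slides 1, 5 and 6 gave -1.50, -1.42 and -0.13, and the median was -0.34 with no filter (adjusted p = 1e-05) and -0.20 with normexp (adjusted p = 0.000107). S100a8 (-1.30), S100a9 (-1.26) and Mpo (-0.995) fell when adjusted over the list alone, with 0 past the threshold over all probes.

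The list of growth hormone and male-biased genes rose by 0.28 (15 of 19, adjusted p = 0.0163, adjusted p = 0.404 with an estimated correlation), with Hsd3b5 at 1.08 and Elovl3 at 1.11. Female-biased genes fell by 0.34 (13 of 13, adjusted p = 0.0163, adjusted p = 0.827 with an estimated correlation), with the steroid hydroxylase Cyp17a1 at -0.55. Cholesterol synthesis genes fell by 0.22 (15 of 21, adjusted p = 0.0176, adjusted p = 0.988 with an estimated correlation), with Insig1 at -0.50 and Mvk at -0.77. No member of the 3 lists passed over the list alone. The male-biased call was lost without AAV-GFP replicate 1 or 4 or PBS replicate 1 or 3 (adjusted p = 0.0776 to 0.188), and its median was 0.15 without AAV-GFP replicate 3 and 0.18 without PBS replicate 1. The female-biased call was lost without AAV-GFP replicate 3 (-0.04) or 4 or PBS replicate 1 (-0.16) or 4 (adjusted p = 0.127 to 0.801). Its median lay between -0.51 and -0.67 without AAV-GFP replicate 1 or 2 or PBS replicate 2 or 3. The cholesterol call was lost without AAV-GFP replicate 1 or 3 or PBS replicate 1 or 4 (adjusted p = 0.0733 to 0.435), with a median of -0.12 without PBS replicate 1 and -0.39 without AAV-GFP replicate 2. Blocked by slide, the medians were 0.14 (adjusted p = 0.459), -0.11 (adjusted p = 0.453) and -0.21 (adjusted p = 0.0162). Within slides 1, 5 and 6 the male-biased median was 0.04, 0.10 and 0.24, the female-biased median 0.40, 0.17 and -0.83, and the cholesterol median -0.58, 0.02 and 0.03. Array weights ended all 3 calls, with medians of 0.16 (adjusted p = 0.0625), -0.13 (adjusted p = 0.87) and -0.25 (adjusted p = 0.266), and quantile scaling ended the male-biased call (0.18, adjusted p = 0.225). Principal components as covariates ended the female-biased call (adjusted p = 0.189 with 1 and 0.185 with 2) and the cholesterol call (adjusted p = 0.0904 and 0.103), and with 2 the male-biased median was 0.17.

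Pck1 and G6pc were higher in AAV-GFP than in PBS, at 0.72 (SE 0.27) and 1.29 (SE 0.57, n = 4, limma adjusted p = 0.999 each), and G6pc was at 0.81 without PBS replicate 1. The whole gluconeogenesis list stood at a median of 0.01 (10 of 20 positive, camera adjusted p = 0.777) and glucocorticoid-induced genes at 0.16 (adjusted p = 0.0699). Fkbp5 was at 0.16 on its brightest probe (SE 0.62) and at -0.98 and -0.59 on its other 2, Tsc22d3 at 0.32 (SE 0.33, its 3 probes at -0.09 to 0.32) and Per1 at 0.11 (SE 0.56), and of these Fkbp5 and Per1 turned sign under other settings. Limma called 0 probes (lowest adjusted p = 0.999), with 448 at an unadjusted p under 0.05, 58 at p under 0.01, and 250 without overlap (0.94%, against 2.86% by chance). Blocked by slide, it called 0, and 25 probes had p under 0.01. The genes of lowest p were Derl3 (3.09-fold), Slc35f1 (at least 1.2-fold, its other probe at -0.76), Fam3b (2.43-fold), Angptl4 (2.15-fold) and Spag5 (2.27-fold) among those higher. Derl3 rose when adjusted over the B cell and plasma cell list alone. Among those lower they were Ephx3 (at least 1.71-fold), Clcn6 (at least 1.47-fold), Olfr1230 (-1.07), Zfp521 (-0.84) and Sybu (at least 1.52-fold). Camera called 5 lists, and 0 with an estimated correlation or by fry. The other 24 had adjusted p of 0.0699 to 0.984. Median and mean differed in sign for p53 targets (-0.03 and 0.10, direction up), bile acid genes (-0.03 and 0.03, up), B cell markers (-0.17 and 0.02, down), ER stress (0.07 and -0.07, down), NRF2 targets (0.02 and -0.12, down), circadian (0.02 and -0.05, down) and adipocyte genes (0.01 and -0.03, down). Camera pointed down for endothelial and acinar genes, whose medians and means were positive. The count was 3 without AAV-GFP replicate 1 or 4 or PBS replicate 4, and 8 without PBS replicate 1 or 2.

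Against PBS, AAV-hGRB livers again had all 30 interferon list members higher, by a median of 1.30 (2.47-fold), and 24 rose when adjusted over the list alone, with 0 over all probes. Means were 2.69 ± 0.66 in AAV-hGRB and 1.26 ± 0.30 in PBS (SD, n = 4, exact permutation p = 0.0286, the smallest possible). Isg15 was 4.95-fold higher, Ifi44 7.37-fold, and the viral RNA sensor gene Ddx58 3.24-fold. Camera's adjusted p was 2.76e-45 and fry's 0.0311, but the call was lost with an estimated correlation (adjusted p = 0.071 with an estimated correlation). Within slides 5 and 6 the median was 0.77 and 1.86. With the slide as a block it was 1.05 (camera adjusted p = 5.49e-22), and 0 members then passed over the list alone.

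Targets of p53 rose by 0.48 (14 of 17, camera adjusted p = 5.23e-07, adjusted p = 0.111 with an estimated correlation, exact permutation p = 0.0286). Phlda3 (1.85), Cdkn1a (1.61) and Eda2r (at least 4.19-fold) rose when adjusted over the list alone, and 0 passed over all probes. The median was -0.23 within slide 5, 0.63 within slide 6 and 0.35 with the slide as a block (adjusted p = 0.00125), and normexp gave 0.32. Cell cycle genes rose by 0.40 (15 of 18, adjusted p = 7.64e-06, adjusted p = 0.339 with an estimated correlation), with Plk1 at 1 and Mki67 at 0.87. Their median was 0.61 without PBS replicate 4 and 0.22 with the slide as a block (adjusted p = 0.00125). It was -0.16 within slide 5 (7 of 18 positive) and 0.96 within slide 6, and 2 principal components ended the call (adjusted p = 0.0653).

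Kupffer cell markers rose against PBS by 0.53 (16 of 16, adjusted p = 7.64e-06, adjusted p = 0.339 with an estimated correlation) and T cell and NK cell markers by 0.46 (12 of 17, adjusted p = 0.00215, adjusted p = 0.339 with an estimated correlation), with 0 members of either past the threshold over the list alone. Their exact permutation p was 0.114 and 0.286. Cd68 stood at 0.57, the scavenger receptor Marco at 0.89, and Gzmb at 1.34. PBS replicate 1 was low in both lists, at 0.92 for Kupffer cell markers (other PBS arrays 1.76 to 1.81) and -2.43 for T and NK markers (others -1.61 to -1.54). Without it the medians were 0.24 and 0.14, and both calls stood (adjusted p = 0.00178 and 0.0309). Without AAV-hGRB replicate 3 they were 0.30 (adjusted p = 0.00548) and 0.25 (adjusted p = 0.0742), which ended the T and NK call. The slide as a block ended both, at 0.11 (adjusted p = 0.147) and 0.25 (adjusted p = 0.0568). Within slides 5 and 6 the Kupffer median was -0.47 and 0.84, and the T and NK median -0.13 and 0.70. With 2 principal components both calls were lost (0.19, adjusted p = 0.123, and 0.08, adjusted p = 0.493), and the stricter filter ended the T and NK call (adjusted p = 0.0736), whose median was 0.28 with array weights and 0.30 with normexp.

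Erythroid genes fell by 0.64 (6 of 6, adjusted p = 0.00522, adjusted p = 0.339 with an estimated correlation), with Slc4a1 at -0.95. That call was lost without PBS replicate 4 (-0.34, adjusted p = 0.158), and the median was -1.04 without PBS replicate 2 and -0.75 with the slide as a block (adjusted p = 0.0173). Array weights ended it (-0.11, adjusted p = 0.77), 2 principal components gave -1.07, and slides 5 and 6 gave -1.06 and -0.70. Glycolysis and lipogenesis genes fell by 0.30 (15 of 20, adjusted p = 0.0471, adjusted p = 0.592 with an estimated correlation), with the pyruvate kinase gene Pklr and Gpam at -0.60 each. That call was lost without AAV-GFP replicate 3 or 4, AAV-hGRB replicate 3 (-0.19) or 4 or PBS replicate 2 (adjusted p = 0.0549 to 0.423), with the slide as a block (-0.27, adjusted p = 0.396) and with quantile scaling (-0.16, adjusted p = 0.105). Median scaling, no filter, the slide as a random block and principal components ended it as well (adjusted p = 0.0511 to 0.352), array weights gave -0.56 (adjusted p = 0.000415), and slides 5 and 6 gave 0.07 and -0.55. Gluconeogenesis genes stood at -0.21 (17 of 20 negative, camera adjusted p = 0.133, exact permutation p = 0.0286). Pck1 and G6pc themselves were near even, at 0.10 (SE 0.27) and -0.08 (SE 0.57). Glucocorticoid-induced genes stood at -0.01 (camera adjusted p = 0.446, direction up), with Fkbp5 at 0.24 (its 3 probes at -0.73 to 0.24), Tsc22d3 at 0.18 (0.02 to 0.18) and Per1 at -0.21. The signs of these 5 genes turned under other settings. Neutrophil markers stood at -0.40 (8 of 8 negative, adjusted p = 0.057), and Mpo fell by 1.11 when adjusted over the list alone.

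**Figure D3:**
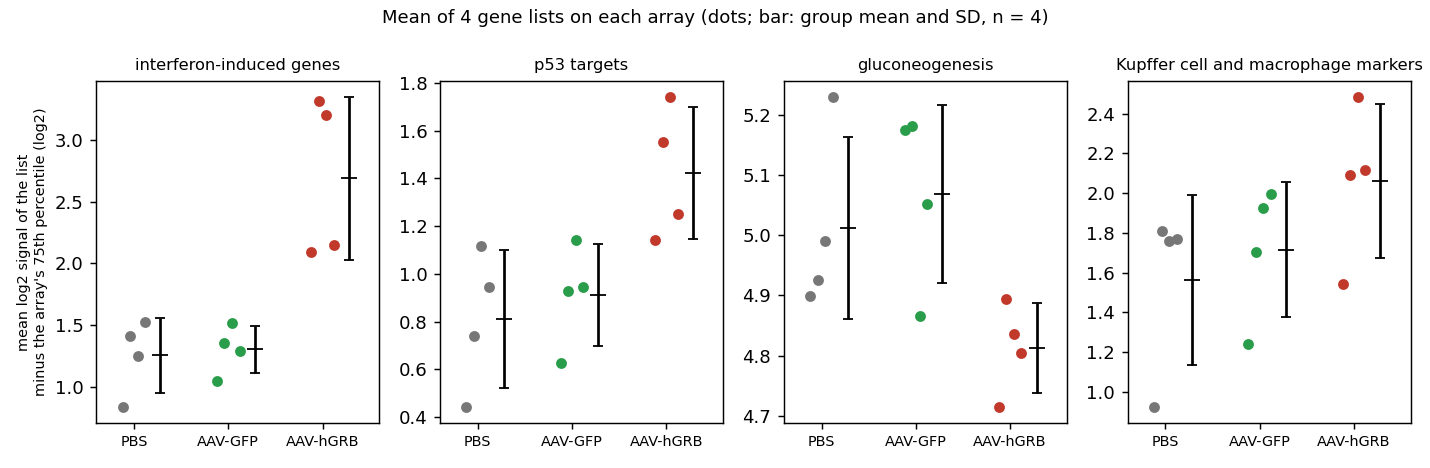
Mean log2 signal minus the array's 75th percentile (y axis) of 4 gene lists on each array, by group (dots), with bars for the group mean and SD (n = 4). In the interferon list the AAV-hGRB arrays lie between 2.09 and 3.32 and the 8 control arrays between 0.84 and 1.53.

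Limma called 0 probes in AAV-hGRB against PBS (lowest adjusted p = 0.102), with 1553 at an unadjusted p under 0.05 where 1330 would be expected, 329 at p under 0.01 where 266 would be, and 1221 without overlap (4.59%, against 2.86% by chance). Array weights gave 67 calls, 56 of them higher. They set PBS replicate 2 at 3.34 (other PBS arrays 0.58 to 0.79) and AAV-hGRB replicate 2 at 2.29 (others 0.83 to 1.34). AAV-GFP replicate 3, which enters only the spread of this comparison, was set at 0.16. Blocked by slide, limma called 0, and 122 probes had p under 0.01. The genes of lowest p were Samd9l (3.76-fold), Fbxo39 (4.14-fold), Usp18 (5.19-fold), Trim30a (4.63-fold, its 2 probes at 1.24 and 2.21) and Oas1c (3.81-fold) among those higher, at adjusted p of 0.164 to 0.197. Those lower were Olfr1230 (at least 2.21-fold), Hamp2, a relative of the iron hormone hepcidin (-2.11), Mmd2 (-2.79), Ephx3 (-1.33) and Pcyt1b (-1.30, its other probe at -0.32), at adjusted p of 0.174 to 0.456. All 10 but Pcyt1b passed with array weights. Each of those lower was also lower in AAV-GFP against PBS, with Olfr1230 at -1.07, Hamp2 at -1.065, Mmd2 at -1.95, Pcyt1b at -0.765 and Ephx3 at least 1.71-fold lower. In AAV-hGRB against AAV-GFP, Hamp2 stood at -1.049, Mmd2 at -0.845 and Pcyt1b at -0.533, and Olfr1230 was at least 1.05-fold lower. Ephx3 stood at -0.08 there, but it was well above background on only 1 AAV-hGRB array and 0 AAV-GFP arrays. Among lists not called, median and mean differed in sign for MHC class II (-0.01 and 0.06), endothelial (-0.02 and 0.03), immediate early (-0.04 and 0.01) and stellate cell genes (0.003 and -0.02), and camera pointed up for these and for the ER stress and male-biased lists, whose medians (-0.03 and -0.04) and means (-0.12 and -0.04) were negative. Camera called 7 lists, fry 1, and camera with an estimated correlation 0. It called 4 with the slide as a block.

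At the adjusted threshold 0 probes were shared by both comparisons of AAV-hGRB, since limma called 0 in either. At an unadjusted p under 0.01, 110 probes were higher than both AAV-GFP and PBS and 3 were lower. The comparisons share the AAV-hGRB arrays. When unchanged AAV-hGRB groups were simulated against the same control arrays, 0.3 higher probes were shared on average (at most 2 in 100 draws), and independent lists of these sizes would share 1.36 higher and 0.19 lower. Regroupings of the real arrays shared far more. Of 100 drawn, the real one included, 5 shared at least the real 113 probes in both directions (highest other 987), so chance is not excluded for this overlap. When the AAV-hGRB arrays were split, so that each control was set against its own 2 of them, 31.8 higher probes were shared on average over 6 splits (20 to 41). Pooling both control groups into 8 arrays, an analysis added after the data were seen, limma called 8 probes, all higher: BC013672 (3.16), Samd9l, Fbxo39, Usp18, Irf7 and further probes of Ifi44 (3.44), Ddx58 and Ifih1, with adjusted p of 0.0247 to 0.0358. BC013672, outside the rule for named genes, was chosen after its values were seen. Leaving out 1 array changed this count to between 0 and 24. It was 0 without AAV-GFP replicate 2 or 4, AAV-hGRB replicate 2 or 3, or PBS replicate 1 or 2, 1 without AAV-GFP replicate 1 or PBS replicate 3, 2 without PBS replicate 4, 5 without AAV-hGRB replicate 1, 18 without AAV-hGRB replicate 4 and 24 without AAV-GFP replicate 3.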

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

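Chosen only after the result was seen were the tests of slides, of the vector particle, of both explanations for the gluconeogenesis list and of brightness, and the splits for the interferon list and for the adjusted probe counts. The other splits and the leukocyte test were set out before.

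In 10 of 204 groups of 4 arrays, 1 array lay far from the other 3, where chance would give about 10.2. AAV-GFP replicate 3 did so 4 times. Its mean of the fatty acid oxidation list was 4.55 (other AAV-GFP arrays 5.38 to 5.54), its Pck1 level 9.06 (8.04 to 8.21), its Oas1c level -0.96 (-1.59 to -1.51) and its Fam3b level -2.88 (-3.75 to -3.71). PBS replicate 1 also did so 4 times. Its means were -1.08 for MHC class II genes (other PBS arrays 0.22 to 0.47), -2.43 for T cell and NK cell markers (-1.61 to -1.54), 0.92 for Kupffer cell markers (1.76 to 1.81) and 5.52 for xenobiotic metabolism genes (5.12 to 5.16). AAV-hGRB replicate 1 did so 2 times, at 1.02 for endothelial markers (0.65 to 0.71) and 3.71 for Car14 (2.76 to 2.78).

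A probe of Ifnb1, the interferon beta gene, was too dim to enter the comparisons, but it was well above background on 2 of the 4 AAV-hGRB arrays and on 0 of the 8 control arrays. Its levels were -4.03 and -2.93 on AAV-hGRB replicates 2 and 3, -6.41 and -6.52 on replicates 1 and 4, and at most -5.46 on a control array. Replicates 2 and 3 also had the highest means of the interferon list, 3.32 and 3.20. Chance alone brings such probes too, since 206 dim probes were well above background on at least 2 AAV-hGRB arrays and no others, 85 for AAV-GFP and 228 for PBS.

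The interferon list was higher in AAV-hGRB than in both control groups, and the real split gave the largest median of all 35 in each comparison. That is 1 of 35 against AAV-GFP (1.31, highest other 1.12) and 1 of 35 against PBS (1.30, highest other 1.13). More leukocytes in the tissue would raise abundant leukocyte genes at least as much, but these differed by 0.354 (95% confidence interval -0.25 to 0.96) where the list's mean differed by 1.39, which argues against that as the whole cause. The vector particle as the whole cause is argued against by the AAV-GFP minus PBS difference of 0.047 (-0.65 to 0.74) beside 1.43 for AAV-hGRB minus PBS; the bound for this test was changed from a part of that difference to all of it after the value was seen, and a share up to 0.74 is not excluded. With the slide as a block the difference from AAV-GFP stayed at 1.279 (1.39 without it), and within slides 5 and 6 the median was 0.82 and 1.79 (25 and 26 of 30 positive), but slides stay open as a cause because the interval of -0.20 to 2.76 on 4 residual degrees of freedom reaches 0, and a response to the human GR beta cargo, or to another difference between the vector preparations, may account for the rest but was not tested.

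The gluconeogenesis list was lower in AAV-hGRB than in AAV-GFP, and 1 of 35 splits gave a median as large (0.254, highest other 0.252). The dim AAV-GFP replicate 3 is argued against as the cause, because without it the median was -0.315. Whether AAV-GFP lay high or AAV-hGRB low cannot be told apart, since the difference from PBS was -0.199 with an interval of -0.41 to 0.01 and AAV-GFP minus PBS was 0.06 (-0.15 to 0.26). The call was lost with quantile scaling, median scaling (adjusted p = 0.054), no filter on dim probes (adjusted p = 0.15) and the slide as a fixed block (adjusted p = 0.117), and without any 1 of AAV-GFP replicates 1, 2 and 4 and AAV-hGRB replicates 1 and 4 (adjusted p = 0.0618 to 0.201).

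AAV-GFP replicate 3 stood apart on the first principal component, which held 41.8% of the variance. Over the 12 arrays this component followed the brightness of the array (Pearson's r = 0.912, permutation p = 3e-04, adjusted p = 6e-04; Spearman's rho = 0.783, permutation p = 0.00382, adjusted p = 0.00382, over 2 correlations). Without AAV-GFP replicate 3 and PBS replicate 3, the arrays farthest from the median, r was 0.763 (permutation p = 0.0102). Brightness is thus a candidate explanation. Hybridisation, labelling and RNA quality could each set it and were not tested, and no biological explanation was tested.

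For the adjusted counts, all 35 of 35 splits of each comparison gave at least the real count of 0, and the highest other was 0, so these counts say nothing about chance. Probes at an unadjusted p under 0.01 do not exclude chance. Against AAV-GFP 8 of 35 splits gave as many as the real 211 (highest other 1877), for AAV-GFP against PBS 28 of 35 (58, highest other 2060), and for AAV-hGRB against PBS 4 of 35 (329, highest other 561). The splits with 1877 and 2060 part the 4 arrays lowest on the first principal component from the rest and point to a structure of the arrays. The split with 561 parts the arrays of slides 5 and 6 from the others, and with the slide as a block the real count was 122. Chance was not excluded either for the number of lists called, with 8 of 35 (10, highest other 17), 24 of 35 (5, highest other 10) and 24 of 35 (7, highest other 15), or for the interferon list in AAV-GFP against PBS, with 28 of 35 (0.09, highest other 0.31).

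Of 100 drawn regroupings of the 12 arrays, 5 shared as many probes at an unadjusted p under 0.01 as the real 113 (highest other 987), which does not exclude chance. With both control groups pooled, 2 of 100 gave as many calls as the real 8 (highest other 526), which is under the 0.05 threshold.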

How the results depend on the processing

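Added after the data were seen were the principal components as covariates, quantile scaling with a trend, and the pooled control groups. Among single genes and lists, 4236 values kept their direction and side of the threshold, 141 fell short of it, 13 newly passed it and 53 turned sign. No gene passed in the reported fit, so all 141 that fell short are lists. The main results are the interferon list and counts of probes, list members and called lists. Of these, 340 were kept, 30 weakened, 11 strengthened and 5 turned sign. A count was taken as kept if it was within 1.5 times the reported count, and counts of 0 that stayed 0 are among those kept. The intensity trend and the fit of only the 2 groups compared kept 159 of 159, and the series matrix moved nothing because its values are those of the scanner files. The replicate numbers gave no clear sign of pairing, which does not settle whether they pair the samples. Of 12 same-number pairs, 5 correlated above 0.1 once group means were removed, and the 12 correlations ran from -0.434 to 0.594. With the number as a block 158 of 159 stayed, and cholangiocyte markers lost their call (adjusted p = 0.0549). Under the scalings tried, the median change of all tested probes lay between -0.06 and 0.05. Low signal limits the rest, since 14581 probes were too dim to test. Unless stated, the cause was not tested.

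The 5 lists called in AAV-GFP against PBS became 0 with an estimated correlation, 0 with fry, 3 with the first principal component and 8 with normexp, and 3 to 8 with an array left out. The 10 against AAV-GFP became 1 with an estimated correlation, 1 with fry, 5 with 2 components, 6 with median scaling and 4 with the slide as a fixed block, and 4 to 14 with an array left out. The 7 in AAV-hGRB against PBS became 0, 1, 3 (2 components), 16 (normexp) and 4 (slide). The interferon median in AAV-GFP against PBS (0.09) became -0.051 with array weights, -0.025 with 2 components, -0.026 with the slide, and -0.047 to 0.162 with an array left out. In AAV-hGRB against PBS its median stayed 1.302 with an estimated correlation but the call was lost (adjusted p = 0.071). Interferon members called over the list alone fell to 0 and 0 from 23 and 24 with the slide as a block. That block leaves 4 residual degrees of freedom and only AAV-hGRB replicates 1 and 3 to inform the difference.

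At an unadjusted p under 0.01, by construction a looser threshold, the counts of 0 became 211, 58 and 329, and 113 were shared. Array weights gave 67 calls in AAV-hGRB against PBS. The 8 calls with pooled controls became 0 to 24 with an array left out.

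Signs turned mostly for small changes. In AAV-hGRB against AAV-GFP, Ehf, at -0.94 in the reported fit, was 0.064 with normexp, Gclc (0.285) -0.043 with the slide, neutrophil markers -0.117 with no filter, Fkbp5 -0.008 with quantile scaling and -0.008 with the trend added (-0.362 to 0.679 with an array left out), Nr3c1 -0.01 with normexp (-0.028 to 0.117), Per1 0.036 and Tsc22d3 0.011 with array weights (Tsc22d3 -0.436 to 0.113). In AAV-GFP against PBS, Fkbp5 was -0.256 with array weights, -0.08 with 2 components and -0.204 with 1 (-0.438 to 0.603), Nr3c1 0.021 with median scaling and 0.02 with normexp (-0.104 to 0.068), and Per1 -0.464 with array weights, -0.06 with 1 component and -0.028 with normexp (-0.474 to 0.496). In AAV-hGRB against PBS, Fkbp5 was -0.09 with 1 component (-0.135 to 0.494), G6pc 0.061 with array weights and 0.031 with either quantile setting (-0.567 to 0.237), Nr3c1 -0.024 with array weights and -0.076 with 2 components (-0.035 to 0.084), Pck1 -0.132 with 2 components, -0.016 with 1, -0.041 with normexp and -0.12 with the slide (-0.055 to 0.246), Per1 0.251 with 2 components and 0.565 with the slide (-0.801 to 0.168), and Tsc22d3 -0.104 with 2 components (-0.113 to 0.366).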

Other observations

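The tests of this part were chosen after the data were seen, except the list of abundant leukocyte genes, which was written before its values were seen. Genes that leukocytes hold at high level stood somewhat above both controls in AAV-hGRB, 11 of 12 of them against AAV-GFP (median 0.37) and 12 of 12 against PBS (median 0.42). Lsp1 differed from AAV-GFP by 0.87, Laptm5 by 0.64, the pan-leukocyte phosphatase gene Ptprc by 0.59 and Cd52 by 0.56, while Tyrobp and Fcer1g, adaptors of myeloid receptors, differed by 0.03 and -0.02. Their mean difference from AAV-GFP was 0.35 with a 95% confidence interval of -0.25 to 0.96, so a change of their share was not detectable with these arrays. Set against these genes, the interferon list still stood higher in AAV-hGRB, by 1.03 (0.46 to 1.60) against AAV-GFP and 0.99 (0.42 to 1.56) against PBS, and array by array this difference was 1.27 to 2.54 in AAV-hGRB and 0.58 to 1.14 in the controls.

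The interferon genes themselves were read by 14 probes, of which 7 were bright enough to test. The highest value of the Ifna13 probe in any array of a group was -2 in AAV-hGRB, -1.65 in AAV-GFP and -1.25 in PBS, and that of the tested probe of Ifng, the product of activated T and NK cells, was -2.81, -2.6 and -3.14. On both probes the highest AAV-GFP value is that of replicate 3, the dimmest array. The group means of Ifng were -3.30 ± 0.33 in AAV-hGRB, -3.56 ± 0.66 in AAV-GFP and -3.98 ± 0.97 in PBS (SD, n = 4), so that AAV-hGRB lay 0.26 and 0.68 higher (SE 0.45 each). A single control array weighs on each difference, in opposite directions. AAV-GFP replicate 3 stood at -2.6 (other AAV-GFP arrays -4.06 to -3.65), which lessens the difference from AAV-GFP. PBS replicate 1 stood at -5.36 (other PBS arrays -3.89 to -3.14), which enlarges the difference from PBS.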
